A study of Mus musculus with 8 samples.

How the data were processed

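Gene expression was measured in 4 mouse epithelial cell lines with a single-colour Affymetrix whole-genome expression array, on 8 arrays in all. EpH4 and NMuMG are mammary gland lines, and mProx and MCT are kidney tubular lines. Each line gave 1 array of resting cells and 1 array of cells stimulated with recombinant TGF-β1 at 3 ng/mL and EGF at 3 ng/mL for 24 h. Per the labels' protocols, all cells had first spent 24 h in a medium containing insulin and transferrin, and biotin-labelled total RNA was hybridised. The labels mark EpH4 as resistant to the epithelial-mesenchymal transition (EMT), the change of epithelial cells towards a fibroblast-like state.

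The deposited values are array intensities on a linear scale, 1 signal per probe set and array, for 45101 probe sets. Per the submitters' processing notes they came from MAS5, the Affymetrix algorithm that summarises the perfect-match and mismatch probes of a probe set. Its version and scaling target are not given in the sources used here, and detection calls were not used here. The arrays do not share a scale, since their means after trimming 2% at each end ran from 207 to 375, a ratio of 1.81, and their median signals from 41.5 to 59.6. Actb and Gapdh control probe sets, which compare the 3' with the 5' end of a transcript, gave ratios of 1.11 to 1.20 and 0.776 to 0.823 over the 8 arrays. No batch or scan date is given in the sources used here.

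The following was computed from the deposited intensities. The 64 control probe sets were left out. An offset of 10.6, the 25th percentile of the positive signals, was added before taking log2, which keeps the dimmest signals from giving large ratios and understates changes of dim genes. The arrays' median log2 values differed by 0.43. A rule fixed before the data were examined called for quantile normalization when they differed by over 0.3, so the log2 values were quantile-normalized across the 8 arrays. Quantile normalization removes any change in the overall distribution of signals between resting and stimulated cells.

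Gene symbols came from the platform's annotation table and were checked through Entrez identifiers against the gene table of assembly GRCm38.p6. Of the analysed probe sets, 34945 have 1 symbol, 932 have several and 9160 have none. Of the single symbols 34741 were matched, and 0 changed. Each of 18193 genes was represented by its probe set with the highest mean level, avoiding probe sets marked as cross-hybridising where another existed. One gene of a panel fixed beforehand is not reported here. The 12640 genes whose mean log2 level reached the 40th percentile of all probe sets, 5.27, were tested. The build behind the array's annotation is not given in the sources used here, so no coordinates are printed.

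Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. The cell line is the replicate and the pair, and it entered every test of a response as a block. The pairing comes from the line names, and the 2 arrays of each line deviated together from the means of their groups, with correlations across genes of 0.906, 0.828, 0.813 and 0.876. Nothing in the labels says how many separate cultures lie behind an array, so p-values measure only the spread between these lines. A resting and a stimulated array of 1 line also have no replicate check on their own. The comparisons, fixed before the data were examined, were the response in all 4 lines, the response in the 3 lines not marked as resistant, the difference of the EpH4 response from the other 3, the difference of the kidney from the mammary response, and 2 comparisons of resting cells, kidney against mammary lines and EpH4 against the other 3. Where EpH4 stands alone, or 1 line of a tissue when the other is left out, it is assumed to vary like the other lines.

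Named genes follow a fixed rule. It takes the panel, up to 12 genes each way per response past the threshold, filled where needed with genes changed at least 2-fold the same way in each line, up to 10 each way per difference, filled by the largest moderated t, and up to 4 members of each gene list described. Filled genes are said not to pass. The 24 gene lists, also fixed beforehand, were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry. They are mesenchymal markers, epithelial junctions, TGF-β/SMAD targets, BMP/Id targets, collagens and matrix, integrins, actin cytoskeleton, ERK pathway feedback, matrix proteases, DNA replication, sterol biosynthesis, glycolysis and hypoxia, NRF2 targets, interferon-stimulated genes, NF-kB targets, the unfolded protein response, receptors and SMADs, proximal tubule, kidney developmental, mammary luminal, basal and myoepithelial, fibroblast, endothelial and leukocyte markers. With an estimated correlation, camera also uses only the few residual degrees of freedom that these arrays leave. A call can then be lost whatever the correlation, so such a loss does not show that correlation between genes caused it. Counts of genes changed at least 2-fold per line carry no test, and their agreement between lines was set against 10000 shuffles of genes within 10 bins of mean level.

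The tests were tried on simulated data with 200 changed genes. Gene variances were drawn around those limma estimated for each comparison, which makes them wider on average than the estimates. Each changed gene was shifted by the same amount in every line concerned, whereas real changes vary between lines. The recovered shares describe that setting and are not the power of the tests on these data. For the 4-line response, 63.2% of genes changed by 1 log2 unit and 86.4% of those changed by 2 were recovered, and for the 3-line response 35.3% and 87.9%. For the EpH4 difference 0% and 19.7% were recovered, and for the kidney difference 7.35% and 51.5%. For both comparisons of resting cells, 0% were recovered even at 4 log2 units. The number of arrays limits the precision of every value. Alternatives covered the offset, the normalization, the filter, the intensity trend, all probe sets in place of 1 per gene, the line block, the arrays entering the 3-line fit, and leaving out each line. Scaling each array by 1 factor to a common trimmed mean was added after seeing the data. Figures were drawn with matplotlib 3.10.9.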

Results

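The series compared mouse epithelial cells induced towards EMT with cells that were not. The data were 4 resting and 4 stimulated arrays, 1 of each from the mammary lines EpH4 and NMuMG and the kidney tubular lines mProx and MCT. TGF-β1 is a classical inducer of EMT, and EGF activates the ERK pathway. Median signals per array lay between 41.5 and 59.6 on the deposited scale. Log2 levels of the 2 arrays of a line correlated across genes at 0.967 to 0.984, and those of different lines at 0.790 to 0.909. Below, a gene is called dim in a line where it was under the filter level of 5.27 on an array compared. Sizes that rest on dim values are not exact, and a small change between 2 dim arrays does not show that a gene stayed the same.

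In the response over all 4 lines, 10 genes were changed at least 2-fold the same way in each line, 8 higher and 2 lower, although none of them passed the test. Among the larger mean increases were those of Ctsw, a papain-family protease, with a log2 change of 3.25 ± 1.62 (SD, n = 4), and of Acsbg1, an acyl-CoA synthetase of fatty acid activation, with 3.24 ± 0.78. Tnnt2, the cardiac troponin T gene, was higher by 2.99 ± 1.05. Also higher in each line were Ctla2a, a cysteine protease inhibitor, the ETS transcription factor gene Etv5, the metalloprotease gene Adam12, the laminin chain gene Lamb3, and Flacc1. The 2 lower genes were Sult1c2, a cytosolic sulfotransferase, at -3.01 ± 1.18, and Cys1, a protein of primary cilia, at -1.66 ± 0.38. Sult1c2 was dim in EpH4 and MCT after stimulation, and Cys1 on both arrays of EpH4 and in stimulated MCT and NMuMG. At rest Ctsw was dim in mProx and MCT, Acsbg1 and Flacc1 in mProx, MCT and NMuMG, and Adam12 and Lamb3 in mProx, so these sizes are not exact. In limma's test 0 of 12640 genes passed the threshold, against 1469 at an unadjusted p under 0.05, and the smallest adjusted p was 0.0549 for Acsbg1. Without EpH4, 16 genes passed, and on the values as deposited 236 did.

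The TGF-β/SMAD target list was shifted up (camera adjusted p = 2.18e-11), with a median log2 change of 0.68 and 30 of its 33 tested members higher. Adjusted over the list alone, 20 members rose and 1 fell, against 0 among all genes. Among them Pdgfb, a platelet-derived growth factor chain, rose by 0.92 with an SE of 0.13, Col1a1, a fibrillar collagen chain, by 1.42, Rhob, a small GTPase, by 0.63 and Skil, a repressor of SMAD signalling, by 0.80. Col1a1 was dim at rest in mProx and on both arrays of MCT. The ERK pathway feedback list followed (camera adjusted p = 7.31e-07), with 15 of 36 members risen, adjusted over the list alone, and 0 among all genes. They included the ERK phosphatase genes Dusp4, higher by 0.98, and Dusp5, by 1.65, and the ETS factor genes Etv5, by 1.75, and Etv4, by 1.63. Both calls were lost with an estimated correlation (adjusted p = 0.412).

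Smaller shifts were found for 5 further lists in the 4-line response. Mesenchymal markers (camera adjusted p = 4.53e-05, median 0.23) and the actin cytoskeleton list (0.000871, median 0.14) were shifted up, and so were collagens and matrix (0.044, median 0.08). Over each list alone 2, 5 and 8 of their members rose, among them the growth factor receptor gene Fgfr1 at 0.77, the actin crosslinker gene Flna at 0.38 and Lamb3 at 1.53. DNA replication genes (camera adjusted p = 6.92e-05, median -0.11) and interferon-stimulated genes (0.00111, median -0.20) were shifted down, but not evenly. The DNA replication median was 0.13 in NMuMG and -0.33 in EpH4, and in the 3 lines without EpH4 that list (camera adjusted p = 0.151) and the matrix list (0.165) did not pass. The interferon median was 0.00 in EpH4 and -0.03 in mProx against -0.54 in MCT and -0.39 in NMuMG. No DNA replication member passed over its list alone, whereas Ifit2 and Ifit3, interferon-induced antiviral genes, fell by 0.97 and 1.85, Ifit3 to dim levels in EpH4 and NMuMG. These 5 calls were also lost with an estimated correlation, at adjusted p = 0.412 for the mesenchymal and actin lists, 0.536 for matrix and 0.547 for the other 2. For the mesenchymal list the estimate, 0.0105, was close to the preset 0.01, so its call was not lost through the correlation. The estimate was 0.0405 for actin, 0.0177 for matrix, 0.28 for DNA replication and 0.166 for interferon-stimulated genes. For these lists the adjusted p at the preset may be too small. None of the 5 lists passed fry. Its adjusted p was 0.0932 for mesenchymal markers, 0.114 for actin, 0.253 for matrix, 0.45 for DNA replication and 0.424 for interferon-stimulated genes.

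The other 17 lists did not pass camera in the 4-line response. Their adjusted p was 0.195 for integrins, NRF2 targets and mammary luminal markers, 0.209 for NF-kB targets, and 0.265 for BMP/Id targets, matrix proteases, glycolysis and hypoxia, and endothelial markers. It was 0.307 for fibroblast markers, 0.486 for kidney developmental genes and for basal and myoepithelial markers, 0.618 for the unfolded protein response, and 0.684 for epithelial junctions. It was 0.851 for leukocyte markers and 0.917 for sterol biosynthesis, receptors and SMADs, and proximal tubule markers. The epithelial list had a median of -0.04 with a mean of 0.10, and the proximal tubule list a median of 0.06 with a mean of -0.10, so their signs differ. Keratins Krt8 and Krt18 nevertheless rose by 0.71 and 0.74, adjusted over the epithelial list alone.

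**Figure D1:**
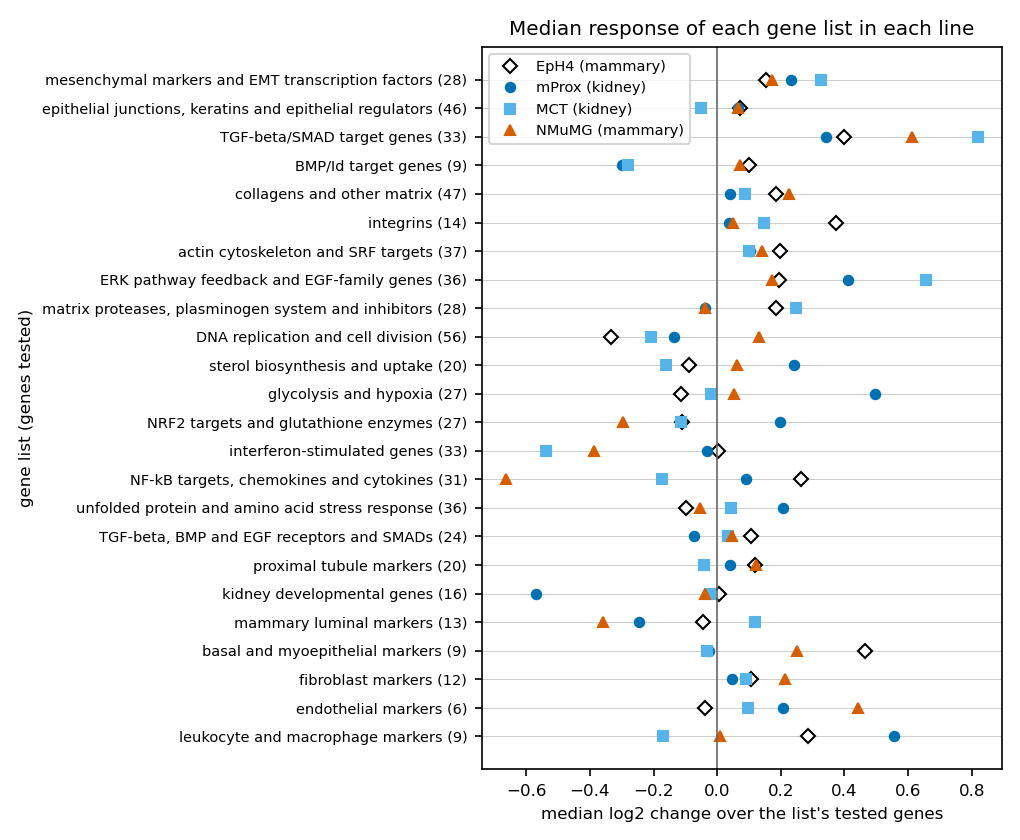
Median log2 change (stimulated minus resting) over the tested genes of each fixed list, 1 point per cell line, with the number of genes tested in brackets. TGF-β/SMAD targets lie above 0 in each line, from 0.34 in mProx to 0.82 in MCT, while NF-kB targets run from -0.67 in NMuMG to 0.26 in EpH4.

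Of the fixed panel, no gene passed the test of the response in either set of lines. Vim, the mesenchymal intermediate filament gene, was near the top of the scale in resting mProx, MCT and NMuMG, at log2 levels of 13.20, 13.26 and 13.31, and near the bottom in EpH4, at 4.02. Cdh1, encoding E-cadherin, was at 11.84 in EpH4 and 10.69 in NMuMG but at 3.53 and 3.87 in mProx and MCT, and its change was -0.62 in NMuMG and -0.23 in EpH4, with 1 array per condition. In mProx and MCT it was dim on both arrays, so its mean change over the 3 lines, 0.00 ± 0.61 (SD, n = 3), does not show that it stayed the same. Epcam was at 12.35 in EpH4 and at 4.12, 6.67 and 3.90 in mProx, MCT and NMuMG. Id2, a BMP-responsive inhibitor of helix-loop-helix factors, changed by -1.94 ± 0.78 in the 3 lines (limma adjusted p = 0.0654) and by -0.13 in EpH4, where its resting level was only 5.63, and over the BMP/Id list alone it fell. Snai2, an EMT transcription factor, changed by 1.16 ± 0.34 in the 3 lines and by -0.19 in EpH4, and over the mesenchymal list alone it rose. It was dim in resting MCT, so this size is not exact.

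The rest of the panel had smaller or less even values. Fn1, encoding fibronectin, changed by 1.43 in mProx and 2.14 in MCT against 0.11 in NMuMG and 0.17 in EpH4. Resting Fn1 was at 13.26 in NMuMG and 12.79 in EpH4, near the top of the scale, so a rise there may not show. Mmp9, a gelatinase, changed by 2.79 in EpH4, the largest increase of that line. It changed by 1.555 in MCT, where it was dim at rest, by -0.34 in mProx, and by -1.44 in NMuMG, where it was dim after stimulation. Over the 3 lines the mean changes were -0.19 for Tjp1, -0.53 for Ocln, 0.32 for Epcam, 0.86 for Krt18, 0.16 for Cdh2, 0.13 for Vim, 0.36 for Acta2 and 0.01 for S100a4. They were 0.78 for Snai1, -0.02 for Zeb1, 0.69 for Zeb2, 0.37 for Twist1, 0.47 for the inhibitory SMAD gene Smad7 and -0.26 for Id1. Ocln, Epcam and Zeb1 each had 1 other tested probe set, which did not share the direction in the 3 lines. Epcam in mProx and NMuMG, Twist1 in mProx and MCT and Ocln in mProx were dim on both arrays. Vim was near the top of the scale in the 3 lines, so a rise there may not show.

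**Figure D2:**
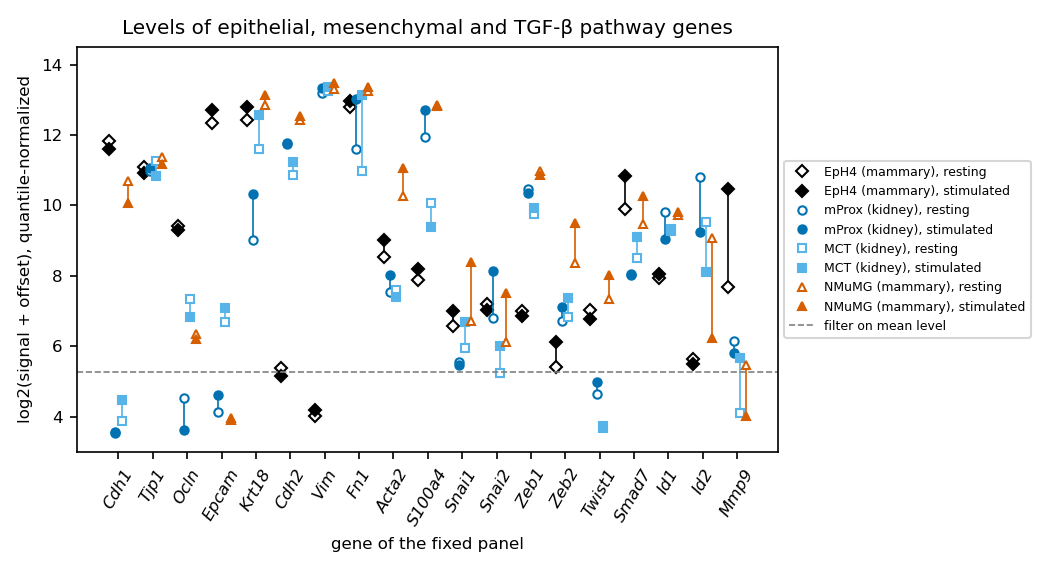
Quantile-normalized log2 levels of 19 panel genes in each line, with open symbols for the resting array, filled symbols for the stimulated array and a dashed line at the filter on mean level, 5.27. Vim stands at 4.02 in resting EpH4 and between 13.20 and 13.31 in the other resting lines, and Id2 drops in mProx, MCT and NMuMG.

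In the 3 lines not marked as resistant, 26 genes changed, 13 rising and 13 falling. Acsbg1 rose by 3.53 ± 0.62 on the log2 scale (SD, n = 3; limma adjusted p = 0.0156) and Tnnt2 by 3.46 ± 0.56 (adjusted p = 0.0117). Resting Acsbg1 was at 3.76, 4.17 and 4.81, dim in each of the 3 lines, so the size of its rise is not exact. Among the other rising genes, Dusp5 rose 4.19-fold, the chromatin protein gene Hmga2 3.18-fold, the prostaglandin synthase gene Ptgs2 2.56-fold, the growth arrest gene Gadd45a 2.55-fold and the Wnt ligand gene Wnt7b 2.41-fold. Ube2cbp, the sodium pump modulator gene Fxyd5, the netrin receptor gene Unc5b, the connexin gene Gja1, the collagen lysyl hydroxylase gene Plod2 and Rhob rose between 1.64-fold and 2.69-fold. Dusp5, Ptgs2 and Ube2cbp were dim in resting mProx.

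Of the falling genes, Sult1c2 fell by 3.52 on the log2 scale, with an SD of 0.72 over 3 lines and an adjusted p of 0.0156 in limma. The uncharacterised gene ccdc198 fell by 3.03, the complement protease gene C1s1 by 2.54 and its partner C1ra by 1.58. Ptgds, which makes prostaglandin D, fell by 2.31 and the ferritin receptor gene Scara5 by 1.94, and Lbp, a plasma protein that binds lipopolysaccharide, fell 3.48-fold. Scel, a cornified envelope protein gene, fell by 1.76, the sodium pump subunit gene Atp1b1 by 1.69 and the glutathione transferase gene Gstm1 by 1.63. P3h2, Ifit2 and the small heat shock protein gene Cryab fell by 1.24, 1.12 and 0.86. After stimulation ccdc198 and Scara5 were dim in MCT and NMuMG, and Sult1c2 and C1s1 in MCT, so the sizes of these falls are not exact. Of the other probe sets, 3 of 4 for Atp1b1 and 1 of 2 for Tnnt2 shared the direction in the 3 lines. The count was 0 without the intensity trend, 0 with no filter and 0 with no line block, and 206 on the values as deposited. It was 10 without mProx and 84 without NMuMG. All of the 24 genes named by the fixed rule kept their direction in each of the 10 settings in which they were refitted. They had been chosen for the same direction in each of the 3 lines, so most of these settings could hardly reverse it, and nothing follows from this.

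**Figure D3:**
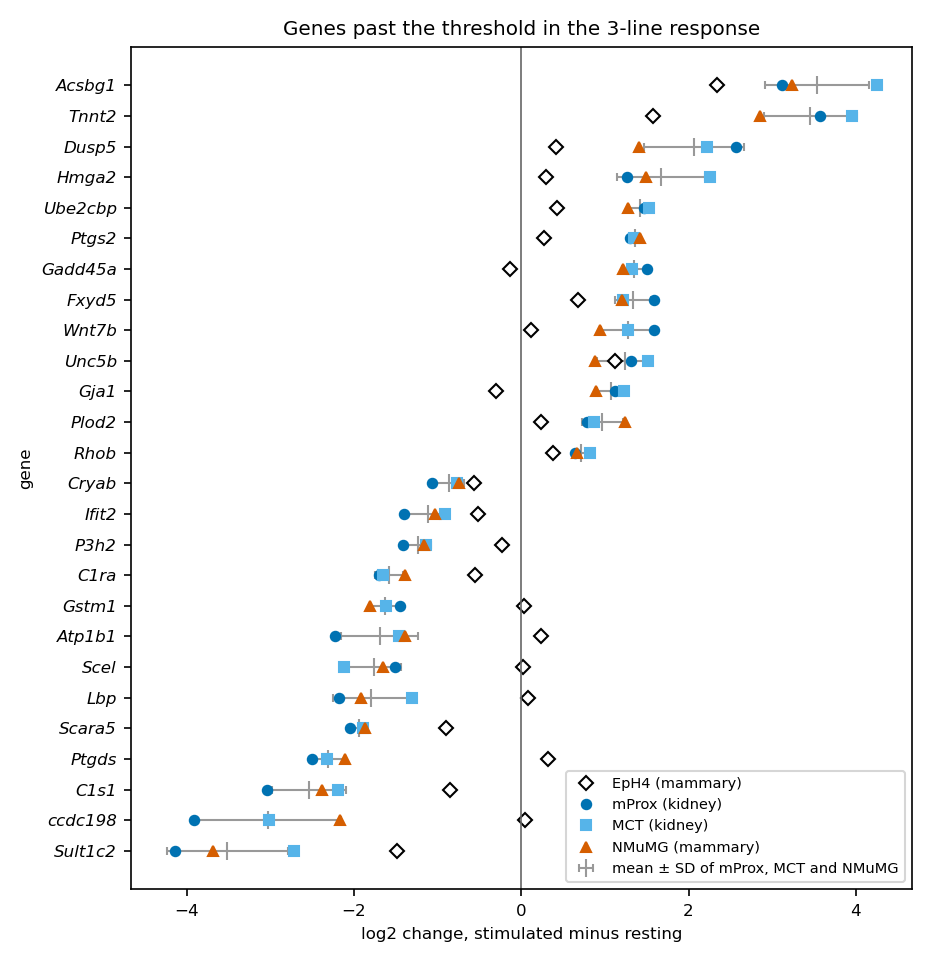
Log2 change (stimulated minus resting, horizontal axis) of the 26 genes past the threshold in the 3-line response, 1 point per cell line, with the mean and SD of mProx, MCT and NMuMG in grey. Open diamonds mark EpH4, which did not enter the estimate, and 18 of them share the sign of the 3-line mean.

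Of the gene lists, TGF-β/SMAD targets were again shifted up in the 3 lines (camera adjusted p = 1.41e-09, median 0.77). Over the list alone 19 of 33 rose and 1 fell, the falling gene being the metalloprotease gene Adamts1 at -1.69, while 2 members, Hmga2 and Rhob, also passed among all genes. The ERK pathway feedback list (2.84e-06) had 9 of 36 members risen, adjusted over the list alone, of which Dusp5 passed among all genes. The mesenchymal list (0.00026) had 2 of 28 and the actin list (0.0404) 2 of 37, and 0 of these among all genes. Interferon-stimulated genes were shifted down (0.00026, median -0.28), with Ifit2 and Ifit3 fallen by 1.12 and 1.98 over the list alone, and so were NF-kB targets (0.0252, median -0.27), whose median was 0.09 in mProx, -0.17 in MCT and -0.67 in NMuMG. In that list Ptgs2 rose and the NF-kB inhibitor gene Nfkbia fell by 0.38, over the list alone. These calls were lost with an estimated correlation, at adjusted p = 0.642 for the 4 lists shifted up, 0.669 for interferon-stimulated genes and 0.799 for NF-kB targets. With fry the mesenchymal list passed (adjusted p = 0.0268). The other lists called here did not pass fry. Their adjusted p was 0.27 for TGF-β/SMAD, ERK and actin, 0.454 for interferon-stimulated genes and 0.71 for NF-kB targets. The estimated correlation was 0.194 for TGF-β/SMAD, 0.164 for NF-kB, 0.0897 for interferon and 0.0691 for ERK. For the mesenchymal and actin lists it was under the preset.

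Matrix, protease, integrin and kidney developmental lists held both rising and falling genes in the 3 lines and did not pass camera. Of 47 collagens and matrix genes 9 rose and 1 fell over the list alone, including Plod2, Lamb3 at 1.68 and Col1a1 at 1.65 (camera adjusted p = 0.165). Of 28 matrix protease genes 4 rose and 2 fell, with Adam12 at 2.01, the stromelysin gene Mmp10 at 2.37 and the inhibitor gene Timp1 at 0.90 among the rising ones (0.477). Of 14 integrin genes 2 rose and 2 fell, the falling ones being Itgb8 at -1.63 and Itga1 at -1.57 (0.988), and the list's median of 0.12 and mean of -0.03 differ in sign. Among all genes, Plod2 alone passed from these 3 lists. In the NRF2 and glutathione list Gstm1, Gstm2 and Gsta4 fell, by 1.63, 1.20 and 0.99 (0.165). In the kidney developmental list Wnt7b rose while Cdh16, a kidney cadherin gene, and the transcription factor genes Foxc1 and Pax8 fell, by 1.59, 0.69 and 0.75 (0.352). Sizes are not exact for genes dim on an array of at least 1 of the 3 lines, namely Lamb3, Col1a1, Adam12, Mmp10, Itgb8, Itga1, Cdh16 and Pax8.

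Genes changed at least 2-fold numbered 299 in EpH4, 665 in mProx, 694 in MCT and 633 in NMuMG. Across all tested genes the log2 changes had an SD of 0.35 in EpH4 and of 0.50, 0.50 and 0.49 in the other 3 lines. In mProx, MCT and NMuMG 21 genes were higher and 25 lower by at least 2-fold in each line, against means of 0.765 and 0.562 in shuffled genes (permutation p = 1e-04 each, the smallest that 10000 shuffles can give). Of these 46 genes, 34 had the same sign in EpH4 and 10 were changed at least 2-fold there. Besides genes named above they included, picked after their values were seen, Smoc1, a matricellular protein gene, Pmepa1 and Ltbp1, both of TGF-β regulation, and among lower genes the peptidase genes Enpep and Mme and the bile acid receptor gene Nr1h4. Resting Smoc1 was dim in all 3 lines, and stimulated Enpep and Nr1h4 in NMuMG and Enpep in MCT. In all 4 lines 8 genes were higher and 2 lower, against shuffled means of 0.0295 and 0.0211 (permutation p = 1e-04 and 2e-04). Changes correlated across genes at r = 0.0827 to 0.170 between EpH4 and the other lines, and at 0.206 to 0.274 among those 3. Genes are not independent replicates, and each line has 1 array per condition, so these counts have no replicate check.

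**Figure D4:**
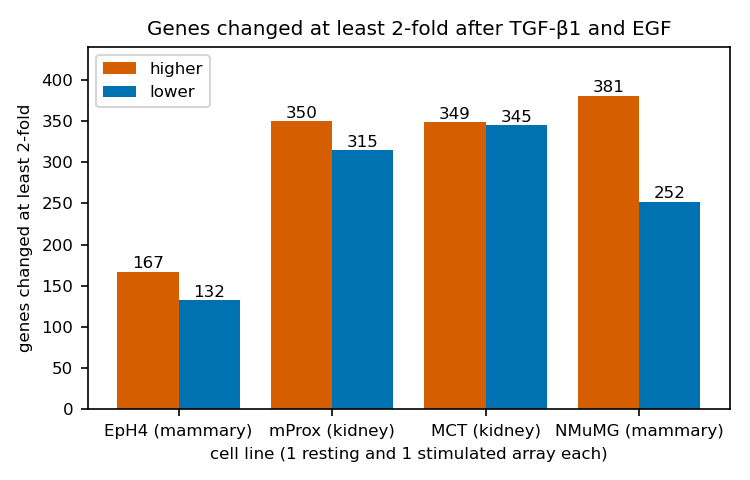
Number of genes (of 12640 tested) higher or lower by at least 2-fold after stimulation in each cell line, from 1 resting and 1 stimulated array per line. EpH4 has 167 higher and 132 lower genes, and the other lines have 349 to 381 higher and 252 to 345 lower genes.

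The difference between EpH4 and the other 3 lines addresses what sets the line marked as resistant apart. Several genes that changed in the 3 lines were near 0 or of opposite sign in EpH4. Ptgds changed by 0.32 in EpH4 against -2.31 in the 3 lines, but its resting level in EpH4, 5.39, is too near the bottom of the scale to show such a fall. Gstm1 changed by 0.04 against -1.63, Gadd45a by -0.14 against 1.35 and Gja1 by -0.30 against 1.08. Nfkbia was higher in EpH4 by 0.62 and lower in the other 3 by -0.38 on average. Atp1b1, Lbp, Tcn2, Smtnl2, Hip1r, Tpcn2 and Vps53 also had larger values in EpH4, and Dpysl3, Zbtb16, Inhba, Sox11, Chst11, Sox13, Pmaip1 and Nr2f1 smaller ones. In EpH4 Sox11, Pmaip1 and Nr2f1 were dim on both arrays, and Smtnl2, Tpcn2, Dpysl3, Zbtb16, Chst11 and Sox13 on 1 of them, so their values there are not exact. In limma's test of the difference 0 genes passed, with 434 at an unadjusted p under 0.05 and a smallest adjusted p of 1.00, so none of these genes is shown to respond differently. On the values as deposited 4 passed.

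Among gene lists, EpH4 differed from the 3 lines by higher values of integrins (camera adjusted p = 0.00469, median difference 0.36), NF-kB targets (0.00634, 0.54), basal and myoepithelial markers (0.011, 0.38) and interferon-stimulated genes (0.0111, 0.25). Over the lists alone Nfkbia passed with a difference of 1.01, Gadd45a of the unfolded protein and stress list with -1.49, and in the basal list Sfn, encoding a 14-3-3 protein of keratinocytes, with 2.27 and the myosin kinase gene Mylk with 2.07. Sfn was dim on both arrays of NMuMG and in stimulated MCT. DNA replication genes (0.000229, -0.26) and the unfolded protein response list (0.0125, -0.17) had lower values. These are differences from the mean of the 3 lines and not from each of them. The lists of TGF-β/SMAD targets, ERK feedback, mesenchymal markers and epithelial junctions were not called. TGF-β/SMAD targets had a median change of 0.40 in EpH4, above the 0.34 of mProx and below the 0.82 of MCT and 0.61 of NMuMG. Median changes in EpH4, mProx, MCT and NMuMG were 0.37, 0.04, 0.15 and 0.05 for integrins, 0.26, 0.09, -0.17 and -0.67 for NF-kB targets, and 0.46, -0.03, -0.03 and 0.25 for basal markers. They were 0.00, -0.03, -0.54 and -0.39 for interferon-stimulated genes, so that mProx was like EpH4, -0.33, -0.14, -0.21 and 0.13 for DNA replication, and -0.10, 0.21, 0.04 and -0.05 for the unfolded protein list. All 6 calls were lost with an estimated correlation (camera adjusted p = 0.618). The estimate was under the preset for integrins and ran from 0.0897 to 0.246 for the other lists called. None of the 6 passed fry, at adjusted p = 0.64 for integrins and 0.804 for the others.

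The kidney lines were compared with the mammary lines to see whether the response followed the tissue of origin. Genes leading the difference were the growth regulator Myc, which changed by 1.72 and 1.57 in mProx and MCT against -0.07 and 0.21 in EpH4 and NMuMG, and Fn1, at 1.43 and 2.14 against 0.17 and 0.11. Ccbe1, a matrix protein gene of lymphatic development, changed by 3.34 and 4.75 against 1.10 and 0.75, Fbln2, encoding fibulin, by 1.84 and 2.71 against 0.55 and 0.37, and the cell cycle inhibitor Cdkn2b by 1.55 and 1.38 against -0.37 and 0.15. Trp53inp1, a p53 target, Slc19a2, Tm4sf1, Ddias and Ctla2a followed. On the lower side stood Gas1, a growth arrest gene, at -2.29 and -1.58 against 0.05 and -0.07, with Zap70, Pdxk, L1cam, Mylip, 4933413J09Rik, Pde4d, Samhd1, Glcci1 and Vegfc. Gas1 and Cdkn2b were dim on both arrays of EpH4, and Vegfc on both of MCT, so these values do not show that they stayed the same there. Resting Fn1 was near the top of the scale in EpH4 and NMuMG, at 12.79 and 13.26, so a rise there may not show. Ccbe1, 4933413J09Rik, Pde4d and Glcci1 were dim on 1 array of at least 1 line. None of these genes passed limma's test, which called 0 genes with 747 at an unadjusted p under 0.05 and a smallest adjusted p of 0.508. The count was 19 without mProx, 57 without MCT and 19 on the values as deposited. In the first 2 of these 1 kidney line stands against 2 mammary lines and is assumed to vary like them.

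The kidney and mammary responses differed in 3 lists. ERK pathway feedback genes were higher in the kidney lines (camera adjusted p = 0.000229, median difference 0.35), and over the list alone Myc, the phosphatase gene Dusp1 and the cytokine gene Lif passed. The unfolded protein and amino acid stress list was higher too (0.000299, 0.22), with Ddit4, a stress-induced mTOR inhibitor, at 0.76 and Trib3 at 0.94, neither past the threshold over the list alone. Basal and myoepithelial markers were lower (0.0303, -0.56). Median changes in mProx and MCT were 0.41 and 0.66 for ERK feedback, 0.21 and 0.04 for the unfolded protein list and -0.03 and -0.03 for basal markers, and those in EpH4 and NMuMG 0.19 and 0.17, -0.10 and -0.05, and 0.46 and 0.25. With an estimated correlation the camera adjusted p was 0.764 for each list, although the estimate was above the preset only for the unfolded protein list, at 0.0478. None of the 3 passed fry, at adjusted p = 0.212 for ERK feedback and basal markers and 0.348 for the unfolded protein list. At rest the ERK feedback list had a median difference of -0.45 between kidney and mammary lines. Changes are measured from those same resting arrays, so the difference in response is not independent of the one at rest.

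The resting kidney and mammary lines were compared for differences of origin that precede stimulation. Cdh16 stood at a mean log2 level of 11.52 in the kidney lines and 4.79 in the mammary lines, Pax8, a kidney transcription factor gene, at 10.28 against 5.52, and the homeobox gene Hoxa10 at 9.83 against 4.85. Hoxb13, Hoxb9, Hoxb2, Hoxb6, the potassium channel gene Kcnk5, Timeless and Slbp were likewise higher. Cdh1 was at 3.70 in the kidney lines and 11.26 in the mammary lines, and Aqp5, a water channel of secretory glands, at 4.32 against 9.68. Vgll3, Ano1, Map2, Fbln2, Cxcl16, Epb41l4a, Pkp1 and Zfas1 were lower in the kidney lines too. At rest Cdh16, Hoxb9 and Pax8 were dim in 1 mammary line, Hoxa10, Hoxb13, Hoxb2 and Kcnk5 in both, and Cdh1, Aqp5, Ano1, Map2 and Pkp1 in both kidney lines. In limma's test 0 genes passed, with 925 at an unadjusted p under 0.05 and a smallest adjusted p of 0.315, and 6 passed on the values as deposited. With 2 lines against 2, the test recovered no simulated change even of 4 log2 units, at a simulated spread wider than the one estimated here.

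DNA replication and cell division genes were higher in the resting kidney lines for all 56 members tested (camera adjusted p = 2.75e-28, median difference 2.20), and 25 passed over the list alone. Ccnb2, a mitotic cyclin, differed by 3.78, the replication licensing factor Cdc6, dim in NMuMG, by 4.04 and the helicase subunits Mcm4 and Mcm6 by 2.59 and 2.32. For the DNA replication list the median difference of the kidney lines was 1.19 from EpH4 and 3.2 from NMuMG. EpH4 itself was higher than NMuMG by a median of 1.92, so the size of the kidney difference depends on the mammary line compared. With 2 lines per tissue this difference may belong to these lines and not to the tissue. Kidney developmental genes (0.0013, 1.55) were also higher, 6 of 16 over the list alone, as were sterol biosynthesis (0.000493, 0.87), interferon-stimulated genes (0.0086, 0.50) and glycolysis and hypoxia (0.0291, 0.33), none of whose members passed. Lower in the kidney lines were TGF-β/SMAD targets (1.13e-06, -0.96), epithelial junctions (6.37e-05, -0.93), mesenchymal markers (0.0013, -0.65), NRF2 targets (0.00396, -0.64), ERK feedback (0.00608, -0.45) and NF-kB targets (0.0291, -0.44). Single lines carried several of these. The median difference of the kidney lines from EpH4 and from NMuMG was 1.70 and 0.16 for the sterol list, -2.15 and 0.12 for epithelial junctions, -0.28 and -1.08 for mesenchymal markers and 0.24 and -1.53 for NF-kB targets. Against the mammary lines, mProx and MCT differed by 0.06 and 0.67 in glycolysis and hypoxia and by -0.96 and -0.04 in NRF2 targets. These 6 lists are thus not shown to follow the tissue. With an estimated correlation each of these calls was lost, at adjusted p = 0.621 for DNA replication, kidney developmental, TGF-β/SMAD, NRF2, ERK and interferon lists and 0.704 for the other 5. The estimate was 0.802 for DNA replication and 0.901 for sterol biosynthesis, so their adjusted p at the preset may be far too small. It was under the preset for the TGF-β/SMAD, ERK and interferon lists and above it for the rest. None of these lists passed fry (adjusted p from 0.46 to 0.669).

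Resting EpH4 was compared with the other 3 resting lines, and Vim differed most clearly. It was lower in EpH4, at a log2 level of 4.02 against 13.26 ± 0.06 (SD, n = 3; limma adjusted p = 0.0103). The first lies near the bottom and the others near the top of the scale, so neither the size of this difference nor the small spread of the 3 lines is exact. The other 2 Vim probe sets were at 4.85 and 4.22 in EpH4 and between 12.18 and 12.73 in the other lines. Vim was the 1 gene past the threshold, with 1126 at an unadjusted p under 0.05. Next came genes that did not pass. Cldn3 and Cldn7, tight junction claudins, stood at 11.92 and 11.59 in EpH4 against means of 4.30 ± 0.13 and 4.87 ± 0.36 in the other lines (SD, n = 3). Rab25, an epithelial trafficking GTPase, and St14, an epithelial membrane protease, were higher too, with Mapk13, Il23a, Artn, Tmem54, Crabp2 and Tmem47. All of these were dim in each of the other 3 lines. Pcbd1, Pcolce, Fbxo21, Col18a1, Fads1, Rab12, F2r, Agpat4 and Tmem98 were lower, of which Pcbd1, Fbxo21 and Rab12 were dim in EpH4. The Vim call was lost without the intensity trend, with 1 factor per array (an added setting) and when any of the other 3 lines was left out, and 12 genes passed on the values as deposited.

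Epithelial junction genes as a group were higher in resting EpH4 (camera adjusted p = 1.02e-12, median difference 1.99), and 15 of 46 passed over the list alone, among them Cldn3, Cldn7, Rab25 and St14. Sterol biosynthesis and uptake genes were lower, in 20 of 20 members (2.02e-17, median -1.56), and 17 passed over the list alone. They included the cholesterol pathway enzymes Cyp51 at -2.73, Idi1 at -2.45, Nsdhl at -2.47 and Lss at -2.44. Glycolysis and hypoxia genes (0.0219, -0.55) and NF-kB targets (0.0219, -0.91) were lower as groups with no member past the threshold. For NF-kB targets EpH4 differed by -0.12, -0.64 and -1.37 from mProx, MCT and NMuMG, and for glycolysis and hypoxia by -0.36, -0.85 and -0.20. The difference in response of NF-kB targets given above is measured from the same resting arrays, so it is not independent of this one. With an estimated correlation the adjusted p was 0.252 for the sterol list and 0.89 for the other 3, and with fry the sterol list passed (adjusted p = 0.0152). The other 3 did not pass fry, at 0.236 for epithelial junctions and 0.939 for glycolysis and hypoxia and for NF-kB targets. Their estimated correlations were 0.144, 0.266 and 0.248, and that of the sterol list was under the preset. The mesenchymal list did not pass camera (adjusted p = 0.0586), but over that list alone Vim, N-cadherin (Cdh2) at -6.31 and Zeb1 at -3.41 were lower in EpH4.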

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

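The test of an absent stimulus in EpH4 was chosen after the result it addresses had been seen, and the order of the lines was partly known when its test was written.

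EpH4 stood apart from the other lines in the size of its response. Its 299 genes changed at least 2-fold compare with 633 to 694 in the others, and the SD of its changes was 0.35 against 0.49 to 0.50. Single genes named by the fixed rule also set EpH4 apart, namely Ptgs2 (0.27 against 1.30 to 1.42), Gadd45a (-0.14 against 1.22 or more), Ptgds (0.32 against -2.51 to -2.11, but at a resting level of 5.39 in EpH4, too low to show such a fall) and Scara5 (-0.90 against -2.05 to -1.87, where it ended under the filter level of 5.27 in MCT and NMuMG). Of 62 quantities looked at for a line far from the other 3, 9 were found, 6 of them in EpH4, while chance gives about 3.1, or 1 in 20. Since 24 of the named genes were chosen for agreement among the other 3 lines, EpH4 was favoured as the line standing apart.

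Whether EpH4 responded less, or received less of the stimulus, was weighed as a hypothesis. The smaller response did not hold against each line for TGF-β/SMAD targets. Their median change was 0.40 in EpH4, against 0.34 in mProx, 0.82 in MCT and 0.61 in NMuMG. An absent stimulus, or a pair of resting arrays, is argued against by the 46 genes changed at least 2-fold in the other 3 lines, which had a median change in EpH4 of 0.38 in the same direction, above all of 10000 random sets matched on mean level (-0.09 to 0.09 after leaving out 2.5% at each end). The genes may in part be too dim in EpH4, but over the 32 of them at or above the filter level its median was still 0.42. The lowest value of another line over its own left-out genes was 0.82. The interval of 0.27 to 0.90 for EpH4, from resampling genes and not lines, reaches it, which leaves this open. The sets are not alike, since those of mProx, MCT and NMuMG, with 21, 15 and 19 genes, had to change at least 2-fold in EpH4. That choice may in part give EpH4 the smallest median. EpH4 had the smallest median of the 4, place 1, which chance gives in 1 of 4 orders, and the resistance named in the labels stays open as an untested explanation.

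Of values in other lines, Etv5 stood apart at 2.92 in mProx against 1.27 to 1.49, Zeb1 at 0.16 in MCT against -0.13 to -0.11, and the Gapdh 3' to 5' ratio of resting MCT was 0.823 against 0.791 to 0.795.

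A test of the difference between lines passed for 9 list results, all at the preset correlation alone. For EpH4 against the other 3 lines these were integrins at a camera adjusted p of 0.00469, DNA replication at 0.000229, interferon-stimulated genes at 0.0111, NF-kB targets at 0.00634, the unfolded protein response at 0.0125 and basal markers at 0.011. For kidney against mammary lines they were ERK feedback at 0.000229, the unfolded protein response at 0.000299 and basal markers at 0.0303. These are differences of means, and the median changes of NF-kB targets and interferon-stimulated genes in mProx (0.09 and -0.03) lay nearer to EpH4 (0.26 and 0.00) than to NMuMG (-0.67 and -0.39). No single gene passed either difference.

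Other splits of the arrays bear on the 2 counts of responding genes. For the 3 lines, the real split gave 26 genes, and the highest of the other splits gave 0. This was 1 of 10 splits, too few for a share under 0.05. For all 4 lines the real count was 0, which all 32 splits that could be fitted with the line block reach, of 35 in all, so nothing follows from it. The highest other count was 9, from a split that leaves some pairs of arrays together, and splits that part all pairs gave 0.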

How the results depend on the processing

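Scaling each array by 1 factor and the test of a change in total RNA were chosen after seeing the data. On the values as deposited the counts were 236 genes for the 4-line response (109 higher, 127 lower), 206 for the 3-line response (111 higher, 95 lower), 4 for the EpH4 difference, 19 for the kidney difference, and 6 and 12 (10 higher, 2 lower) for the resting comparisons. The deposited scale moves the median change of all genes by -0.28 in EpH4, -0.11 in mProx, -0.25 in MCT and 0.35 in NMuMG. A missing common scale may account for these counts, since with 1 factor per array and no quantile step the 4-line count was 6. For both responses limma's prior degrees of freedom were infinite as deposited, against 4.97 for the 4-line response after quantile normalization. A real change in total RNA stays open. The spike-in controls shifted with the array median in 3 of 4 lines, but hybridization controls are added after RNA extraction and follow the array's scale whatever the RNA per cell, so this test is void and decides nothing. Of 1534 values of named genes and lists under the alternatives, 166 lost and 73 gained a call, and 0 called values changed direction.

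With no offset the 4-line and 3-line counts were 1 and 16, and with the median as offset 8 and 9. The 3-line count was 0 with no filter, 0 without the intensity trend, 0 with no replicate block and 16 on the 6 arrays of the 3 lines alone. The pairing block changed no other count. Leaving out 1 line gave 0 to 16 genes for the 4-line response, 10 to 84 for the 3-line response, 0 to 57 for the kidney difference and 0 for the EpH4 difference and both resting comparisons, so the Vim call was lost. The resting EpH4 count was 0 without the intensity trend, 0 with 1 factor per array and 3 with all probe sets. The cause was not tested. Of the 24 named genes of the 3-line response, 15 still passed with no offset, 9 with the median offset, 21 with 1 factor per array and 24 as deposited.

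Counts of genes changed at least 2-fold moved with the treatment of dim signals, and EpH4 had the smallest in each of 7 alternatives. In the order EpH4, mProx, MCT, NMuMG they were 58, 322, 330 and 243 with the median offset, 79, 347, 354 and 251 with the 60th percentile filter, 847, 1219, 1327 and 1174 with no filter, and 817, 1466, 1518 and 1779 with all probe sets, which count more features. With no offset EpH4 had 556 and NMuMG 976. Genes shared by the 3 lines numbered 74 with no offset, 22 with the median offset, 29 with the stricter filter and 76 with all probe sets, and by the 4 lines 20 and 5 with no and with the median offset. Dim signals, with no detection calls used, limit these counts.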

Other observations

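The test of p53 target genes was chosen after the changes of Trp53inp1 and Cdkn1a had been seen, and these genes were left out of it. Pmaip1, named above among genes with smaller values in EpH4, was kept in the test, so not every gene in it was unseen.

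Some large changes belonged to 1 or a few lines. They were picked after their values were seen, have 1 array per condition and no test. Nt5e, the ecto-enzyme CD73 gene, changed by 5.14 in MCT and 4.44 in NMuMG but by -0.42 in mProx and 0.29 in EpH4. Has2, a hyaluronan synthase gene, changed by 4.31 and 3.06 in the same lines, against 0.98 and 0.21. Resting Nt5e and Has2 were under the filter level of 5.27 in MCT and NMuMG, so these sizes are not exact. The tight junction gene Cldn4 changed by 4.33 in MCT and 1.75 in NMuMG. In mProx the natriuretic peptide clearance receptor gene Npr3 changed by -3.92, against 2.42 in MCT, and Csf1r, the macrophage growth factor receptor gene, by -3.29. The chemokine gene Ccl20 changed by -4.57 in NMuMG and -2.12 in MCT, and the retinaldehyde dehydrogenase gene Aldh1a1 by -3.85 in NMuMG, -1.24 in MCT and 1.19 in mProx, the last 2 from resting levels under 5.27. Lcn2, encoding lipocalin, changed by -3.19 in MCT, -2.99 in NMuMG and -0.61 in EpH4.

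A hypothesis was that p53 target genes respond more in the kidney lines, raised by Trp53inp1 and Cdkn1a, whose changes were 1.18 and 2.00 in mProx, 0.93 and 0.86 in MCT, and -0.02 and -0.44 in NMuMG. Over 29 other p53 targets the median difference of kidney minus mammary was 0.63, above all of 10000 random lists matched on mean level (-0.14 to 0.10 after leaving out 2.5% at each end), and 23 were higher. Their median change was 0.67 in mProx, 0.25 in MCT, -0.04 in EpH4 and -0.15 in NMuMG, the last at percentile 0.41 of the random lists. Higher values in both kidney lines and lower ones in NMuMG thus both enter the difference, and with 2 lines per tissue it may belong to these lines and not to the tissue, and no technical explanation was tested. Among these genes, picked here after their values were seen, Fas, a death receptor gene, changed by 2.59 in mProx, from a level under 5.27, but by -0.44 in MCT, while Mdm2, a p53 inhibitor gene, changed by 0.73 and 0.69.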
